A study of Rattus norvegicus with 3 samples.

How the data were processed

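RNA of rat sciatic nerve was measured in 3 libraries, 1 per group, and each library was counted in 4 tables: mRNA genes, mRNA transcripts, lncRNA genes and lncRNA transcripts. Per the labels' protocols, ribosomal RNA was removed with biotinylated probes, the RNA was broken into fragments of 100 to 300 bp and copied from random primers, with actinomycin D present in the first-strand reaction. The submitters' processing notes name bcl2fastq 2.0, HISAT2, StringTie, DESeq2 and limma without saying what each was used for, and name the mouse build mm10, whereas the row identifiers of the deposited tables are those of rat genes and transcripts. The genome that the reads were aligned to is therefore left open, and the strand setting and filters of the counting are not given in the sources used here. No coordinates are reported.

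The values deposited by the authors are counts, whole numbers per gene or transcript with no normalization. The last column of each deposited table, which held the model library, carried 2 extra text characters after each count, and these were removed before use. As deposited, that column was entered here with the unit other for this reason. The columns of the mRNA tables were assigned to groups from the key given with the series, and those of the lncRNA tables from the letters that also open the sample titles. Of 22608 mRNA genes, 17144 carried a current symbol of the RefSeq gene table of assembly GRCr8 and 19236 a current symbol or a synonym. That table was used for names only. The gene and transcript tables had the same total in each library. Transcripts were assigned to genes through their accessions, which placed 31063 of 55767 transcripts in 16986 genes. For 11209 of those genes the sum of the transcripts equalled the gene count in all 3 libraries. Sums of transcripts leave out the transcripts that were not placed in a gene, so a change with them can reflect those missing counts. The counting of reads that match several genes is not stated, so values of near-identical families are uncertain, among them the Lilrb, Mcpt, haemoglobin, keratin, keratin-associated protein, myosin heavy chain and RT1 genes. The same holds for genes that overlap a partner on the other strand.

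The level of a gene was its CPM, the count scaled to the gene total of its own table, computed here from the deposited counts. Ratios between libraries were computed as log2 of (CPM + 1) in one library over (CPM + 1) in the other, which understates the ratio of low genes. mRNA genes with a mean level of at least 1 CPM over the 3 libraries were kept (14427 genes), and lncRNA genes with a mean of at least 0.5 CPM (13931 genes). A gene was counted as higher or lower at a ratio of at least 2-fold. Each group had 1 library, so no difference has a replicate check, no p-value was computed, and every comparison is one of libraries and not of conditions. Whether a library came from 1 animal or from a pool is not given in the sources used here.

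Counting error set the precision. With exact Clopper-Pearson limits at 95%, a gene at 1 CPM in both the model and the sham library had a ratio interval of 0.733 to 1.39, a gene at 5 CPM one of 0.870 to 1.15 and a gene at 100 CPM one of 0.970 to 1.03. A count of 0 allows up to 3 counts, or 0.0404 CPM in sham, 0.0335 in model and 0.0333 in AKBA. Intervals and floors cover counting error only, since PCR copies are not independent molecules and the spread between animals is not included.

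Before the data were examined, 34 gene lists were fixed, covering the cell types of the nerve, neighbouring tissues and pathways, together with the rule for naming genes. A list needed at least 5 members past the level filter, which 32 lists had. The list of genes encoded in mitochondria had 0 members in the mRNA gene table, and the list of lncRNAs with common names had 1, below the filter. For each list the median log2 ratio was set against 10000 random lists of the same size, drawn from 20 bins of mean level. A list at or above percentile 97.5 is called higher and one at or below 2.5 lower. These percentiles describe these libraries and are no test between conditions. Named genes were, for model against sham and AKBA against model, the 10 highest and 10 lowest ratios among genes with a symbol and a mean of at least 5 CPM. For AKBA against sham they were the 5 each way. For genes moved back toward sham they were the 5 each way with the largest smaller ratio, for lncRNAs the 3 each way at a mean of at least 1 CPM, and within lists the 3 members with the largest ratios and those past 2-fold. A gene at 0 in a library is given by its values only. Some list members that meet the rule are not reported here.

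The procedure was tested on simulated counts for the model against sham comparison, with 200 genes changed 4-fold. At a dispersion of 0.05 between libraries, 187 of the 196 changed genes that were kept (95.4%) passed 2-fold, and 286 of 14210 unchanged genes (2.01%) did so. At a dispersion of 0.1 the same step recovered 87.2% and passed 1405 of 14173 unchanged genes (9.91%), and with counting error alone it passed 0 of 14217. With 32 lists at a dispersion of 0.05, 28 were called after a shift of 0.5 on the log2 scale was planted, and 2 without it. The simulated genes varied independently, so the 2 do not show how often lists whose members vary together are called. In the data, 13 lists were called higher and 9 lower in model against sham, 11 and 10 in AKBA against model, and 11 and 6 in AKBA against sham.

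The alternatives fixed in advance were a pseudocount of 0.1, no level filter, a filter at 5 CPM, TMM and upper quartile scaling, levels from sums of transcripts, thresholds of 1.5-fold and 4-fold, and leaving out the muscle, fat and blood lists. Chosen after seeing the data were leaving out ribosomal RNA rows, genes at 0 in any library or a longer list of 122 muscle genes, and adding the mRNA and lncRNA totals. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and TMM factors came from edgeR 4.0.16 in R 4.3.3. No edgeR test was run.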

Results

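The study asked how sciatic nerve of the rat differed in its transcripts 30 days after a crush injury, and how it differed when the injured animals were treated with AKBA (acetyl-11-keto-beta-boswellic acid, a constituent of Boswellia resin). Total RNA of the nerve of male Sprague-Dawley rats was sequenced in 1 library each for a sham operation, in which the nerve was exposed and left uncrushed, for the crushed nerve without AKBA (model), and for the crushed nerve with AKBA. The library called model here carries only the treatment label control, and it is read as the crushed nerve without AKBA from its title letter M and from the injury model, its AKBA-treated group and the sham group that the series names. The dose and duration of AKBA are not given in the sources used here. The mRNA table held 74184217 counts in sham, 89505656 in model and 90071899 in AKBA, over 22608 genes, of which 17374, 17697 and 18060 had at least 1 count. The lncRNA table held 19245904, 22847792 and 28987731 counts. Values below are CPM in the order sham, model and AKBA unless said otherwise, and none has a replicate.

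The libraries differed in their makeup. Ribosomal RNA rows took 11.5% of the mRNA counts in sham, 4.20% in model and 7.59% in AKBA. Among them were the mitochondrial rows mt-Rnr2 (6.86%, 3.20% and 3.07% in the same order) and mt-Rnr1 (0.936%, 0.589% and 0.404%). The summed level of the 20 skeletal muscle genes was 477, 962 and 7189 CPM, that of the adipocyte genes 14942, 8472 and 4328 CPM, and that of the red cell genes 1193, 1961 and 1182 CPM. The median log2 ratio of all genes was 0.18 for model against sham, -0.04 for AKBA against model and 0.16 for AKBA against sham, and TMM scaling moved the first by -0.20. List medians are therefore given relative to the median of all genes in the same comparison.

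Model against sham addressed what the crush left different in the nerve at day 30. Genes of myelin and of the Schwann cells that make it were higher in the model library. Of 22 measured members 20 were above 0 and 13 were at least 2-fold higher, with a median log2 ratio of 1.07 above all genes (percentile 100). The peripheral myelin protein gene Pmp22 stood at 4503, 11211 and 9417 CPM, and periaxin (Prx) at 889, 2333 and 2207 CPM. Mbp, the myelin basic protein gene, went the other way, at 3012, 1553 and 1335 CPM, and Gjc3 was at 10.8, 8.33 and 34.0 CPM.

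Cholesterol synthesis genes were higher in model than in sham by a similar amount. Of 23 members 17 were at least 2-fold higher, and the median was 1.03 above all genes (percentile 100). Hmgcs1, which makes HMG-CoA, had 482, 1502 and 687 CPM. Insig1, a feedback inhibitor of the pathway, was lower in model, at 322, 202 and 109 CPM.

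Fat cell and fatty acid synthesis genes were lower in model than in sham. The adipocyte list had a median of -0.89 relative to all genes (percentile 0), with 16 of 18 members below 0 and 4 at least 2-fold lower. Adipoq (adiponectin) stood at 2690.2, 1242 and 622 CPM and Lep (leptin) at 355, 172 and 68.6 CPM. The fatty acid synthesis list had a median of -0.61 (percentile 0), with 8 of 17 members at least 2-fold lower. Among them, stearoyl-CoA desaturase Scd had 27955, 3707 and 1013 CPM, and fatty acid synthase Fasn 4989.9, 1599 and 667 CPM. Scd2 was instead higher in model, at 2896, 6379 and 5067 CPM. Thrsp stands in both lists.

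Vessel, perineurial and cell cycle genes were higher in the model library. The endothelial list had a median of 0.75 above all genes (percentile 100), with 6 of 15 members at least 2-fold higher, among them the tight junction gene Cldn5 at 23.8, 75.6 and 83.7 CPM and the transcription factor Sox17 at 17.0, 53.2 and 34.4 CPM. The endothelial gene Vwf was lower in model, at 227, 147 and 206 CPM. The perineurial list had a median of 0.62 (percentile 99.9; 7 of 7 members above 0), and the smooth muscle and pericyte list one of 0.33 (percentile 99.8), with Notch3 at 51.2, 147 and 128 CPM. All 24 cell cycle genes were above 0 and 9 were at least 2-fold higher, with a median of 0.66 (percentile 100). Top2a stood at 15.7, 37.7 and 30.6 CPM and Rrm2 at 2.70, 9.83 and 15.3 CPM.

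Several smaller groups were also higher in model. The non-myelinating Schwann cell list had a median of 0.33 (percentile 99.7), with Ncam1 at 23.0, 64.9 and 41.3 CPM and L1cam at 26.1, 64.5 and 41.9 CPM, both adhesion molecules of these cells. The neuron and axon list had a median of 0.39 (percentile 99.0), with 9 of 9 members above 0 and Uchl1 at 13.3, 41.7 and 18.0 CPM. The immediate early list, which also responds to handling, had a median of 0.54 (percentile 100), with Egr1 at 9.72, 25.4 and 15.5 CPM. The leukotriene list, whose enzyme 5-lipoxygenase is a known target of AKBA, had a median of 0.33 (percentile 97.8), with Ltc4s at 6.93, 16.7 and 8.42 CPM and Alox15 at 2.56, 7.74 and 3.13 CPM. The skeletal muscle list had a median of 0.62 (percentile 100), the red cell list 0.49 (percentile 99.7) and the list of neurotrophic factors and receptors 0.20 (percentile 98.3). Of these calls, the leukotriene one was lost at a pseudocount of 0.1 (percentile 95.8), at the 5 CPM filter (95.9), and with TMM (97.3) and upper quartile scaling (97.2), the neurotrophic one with no level filter (81.8), and the non-myelinating (94.6) and axon (97.3) ones with sums of transcripts, as were the fibroblast (5.69) and neutrophil (5.82) calls given next.

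The macrophage list had a lower median in model (-0.29, percentile 0.04), with 11 of 20 members below 0 and 3 at least 2-fold lower. The share above 0 was 10% with TMM scaling and 15% with upper quartile scaling, and it was also lower than with total counts for complement (20% with both scalings), matrix (23.1%) and oxidative phosphorylation genes (10.5%). The 3 macrophage genes at least 2-fold lower were Gpnmb, a glycoprotein of lipid-loaded macrophages, at 527, 47.0 and 1102 CPM, lysozyme Lyz2 at 1039, 387 and 1196 CPM, and the lysosomal marker Cd68 at 43.7, 20.9 and 60.1 CPM. Csf1r, Adgre1 and C1qa, which mark macrophages broadly, stood at 261, 278 and 208 CPM, at 55.3, 74.1 and 60.7 CPM, and at 182, 196 and 176 CPM. The complement list had a median of -0.30 (percentile 0.10), with C6 at 461, 157 and 97.0 CPM. The fibroblast list had one of -0.34 (percentile 0.175), the neutrophil list -0.46 (percentile 1.37), the oxidative phosphorylation list -0.28 (percentile 0.09), the matrix and collagen list -0.21 (percentile 0.90) and the NRF2 and oxidative stress list -0.17 (percentile 1.76), although its member Nqo1 was higher in model, at 15.0, 31.9 and 26.8 CPM.

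**Figure D1:**
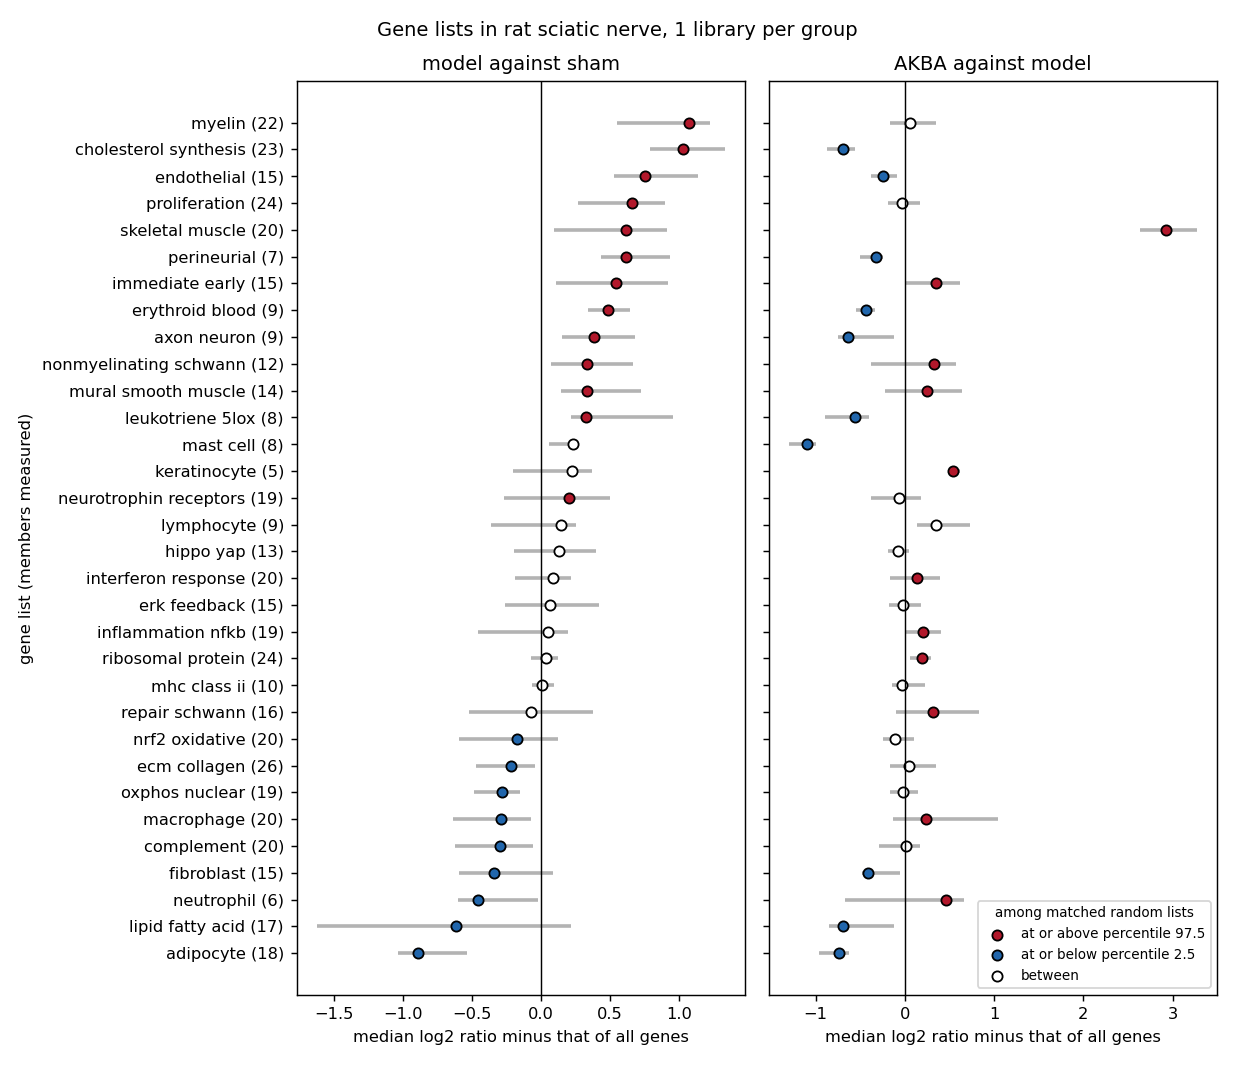
Median log2 ratio of each gene list minus the median of all genes (points) with the range between its quartiles (grey bars), for model against sham (left) and AKBA against model (right); the x axes differ between the panels and each group is 1 library. Myelin (1.07) and cholesterol synthesis (1.03) had the highest medians in the left panel, and skeletal muscle (2.93) the highest and mast cell genes (-1.10) the lowest in the right panel.

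By single genes, 652 mRNA genes were at least 2-fold higher and 189 at least 2-fold lower in model than in sham. With TMM scaling the split was 376 to 293, and with upper quartile scaling 395 to 283. Among the highest were Fam111a (log2 ratio 4.46; 6.43, 163 and 13.3 CPM), Arhgef4 (3.78; 2.28, 44.1 and 4.72 CPM), and the collagen IX chains Col9a1 (3.31; 24.0, 246 and 40.1 CPM) and Col9a2 (2.51). The others were Zfp238 (2.86), Rgs16 (2.69), the node of Ranvier gene Nfasc (2.66; 29.0, 189 and 115 CPM) and the glucocorticoid receptor gene Nr3c1 (2.56; 79.4, 474 and 364 CPM). Col23a1 (0, 33.5 and 13.4 CPM) and Zfp74 (0, 8.45 and 6.87 CPM) were listed at 0 in sham. Among the lowest were the immune cell receptors Lilrb3 (-4.31; 79.1, 3.04 and 50.1 CPM) and Lilrb4 (-3.58; 49.3, 3.21 and 80.6 CPM), Serpina12 (-3.89), Gpnmb (-3.46), Ephx2 (-3.02), Scd (-2.91) and Me1 (-2.88), and the ribosomal RNA precursor Rn45s (-3.87). Rn45s held 2.88% of the mRNA counts in sham, 0.197% in model and 3.60% in AKBA. Ribosomal RNA was removed with probes, so no Rn45s ratio is read here as a change in expression. Selenbp1 had 1590 counts in sham, 1 in model and 1565 in AKBA, with a counting interval of -16.2 to -8.43 for the log2 ratio of model to sham, and Crkl had 9.72, 0 and 10.8 CPM. Since 21 genes were at 0 in at least 1 library and at 10 CPM or more in another, a count at or near 0 is not read here as absence of the transcript.

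AKBA against model addressed how the treated crushed nerve differed from the untreated one. Skeletal muscle genes were the group that differed most. All 20 members were above 0 and 19 were at least 2-fold higher in the AKBA library, with a median of 2.93 above all genes (percentile 100). Titin (Ttn) stood at 207, 444 and 3059 CPM, the fast myosin Myh4 at 73.1, 175 and 1129.9 CPM and skeletal actin Acta1 at 22.3, 48.5 and 485 CPM. Without the longer list of muscle genes, 328 genes were at least 2-fold higher and 195 lower, against 388 and 197 with them.

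Mast cell genes were lower in the AKBA library. All 8 members were below 0 and 6 were at least 2-fold lower, with a median of -1.10 (percentile 0). The proteases Cpa3 and Cma1 stood at 81.9, 117 and 31.9 CPM and at 36.2, 64.8 and 18.1 CPM, and Hdc, which makes histamine, at 6.73, 9.30 and 3.51 CPM. The leukotriene list was lower too (median -0.56, percentile 0), with 7 of 8 members below 0. Its higher call in model against sham uses the same model library, and in AKBA against sham the list had no call (median -0.007, percentile 43.8). Alox5, the 5-lipoxygenase gene itself, had 22.4, 24.9 and 17.3 CPM.

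Cholesterol synthesis genes were lower in AKBA than in model in 23 of 23 members, 3 of them by at least 2-fold, with a median of -0.70 (percentile 0). These 3 were Hmgcs1, Cyp51 (149, 362 and 163 CPM) and Sc5d (89.6, 190.1 and 88.5 CPM). The fatty acid synthesis list (median -0.70, percentile 0) and the adipocyte list (median -0.74, percentile 0; 18 of 18 members below 0) were lower as well, so that Scd, Fasn and Adipoq were ordered sham, model, AKBA from high to low. The myelin list did not stand apart (median 0.06, percentile 94.4; 11 of 22 members above 0). Within it, Pou3f1, a transcription factor of the promyelinating stage, stood at 2.43, 3.13 and 17.0 CPM, Gjc3 at 34.0 CPM in AKBA, and Mog at 1.44, 2.41 and 0.233 CPM. At the 5 CPM filter the list was called higher (percentile 99.4).

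The list of the Schwann cell injury response had a higher median in AKBA than in model (0.32, percentile 99.9), with 11 of 16 members above 0 and 5 below. By at least 2-fold, 4 members were higher and 1 lower. The low-affinity neurotrophin receptor Ngfr had 24.7, 17.3 and 74.6 CPM, Sox2 6.32, 9.13 and 22.3 CPM, the injury-induced factor Atf3 16.5, 21.2 and 49.4 CPM and Runx2 8.99, 3.69 and 9.79 CPM. Shh, also a gene of repair cells, was lower, at 8.41, 29.7 and 10.8 CPM, as were Ncam1 (log2 ratio -0.64), Gap43 (-0.50), Cdh2 (-0.36) and Artn (-0.08). The non-myelinating list, which shares Ngfr, Sox2, Gfap, Cdh2 and Ncam1 with it, had a median of 0.32 (percentile 100; 8 of 12 members above 0). The immediate early list had a median of 0.35 (percentile 100; 10 of 15 members above 0), with Fos at 9.75, 18.7 and 48.5 CPM and Egr1 lower in AKBA than in model.

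The macrophage list was higher in AKBA than in model (median 0.24, percentile 100), but its members differed in direction, with 12 above 0 and 8 below. Gpnmb, Lyz2, Cd68, Trem2 (18.1, 14.3 and 37.5 CPM) and Cybb (67.6, 46.5 and 123 CPM) were at least 2-fold higher, whereas the scavenger receptor Cd163 was at least 2-fold lower, at 165, 213 and 101 CPM. The neutrophil list (median 0.46, percentile 98.8) also went both ways, with Mmp9 at 0.256, 0.525 and 6.54 CPM and myeloperoxidase (Mpo) at 54.4, 42.4 and 14.3 CPM. Of its 12 listed members 6 passed the level filter. Elane (0, 7 and 5 counts), Ltf (0, 7 and 8) and Camp (0, 7 and 13) did not. The list of inflammatory and NF-kB genes had a median of 0.20 (percentile 98.4), with 13 of 19 members above 0 and the chemokine Ccl3 at 2.02, 1.44 and 4.59 CPM. The interferon list (median 0.13) lay just past the upper bound. The neutrophil call, on 6 members, was lost with no level filter (percentile 73.4), the inflammatory one with sums of transcripts (88.1), and the interferon one in 6 settings, among them TMM scaling (97.4) and sums of transcripts (96.3). The macrophage and neutrophil lists were called lower in model against sham, which uses the same model library. In AKBA against sham they had no call (percentiles 68.3 and 2.75).

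The neuron and axon (median -0.64, percentile 0; 7 of 9 members below 0), fibroblast (-0.41, percentile 0; 11 of 15), perineurial (-0.33, percentile 0.95; 7 of 7), endothelial (-0.24, percentile 0.07; 12 of 15) and red cell lists (-0.43, percentile 0.09; 7 of 9) had lower medians in AKBA than in model. The axon, perineurial and red cell lists were called higher in model against sham, which uses the same model library. In AKBA against sham they had no call (percentiles 86.8, 83.0 and 75.7). No perineurial or endothelial member was at least 2-fold lower, and Vwf, Tie1 and Cldn5 were higher (log2 ratios 0.48, 0.21 and 0.15). Uchl1 and the neurofilament gene Nefh (85, 195 and 27 counts) were at least 2-fold lower, while Nefm was at 6.15, 7.32 and 14.1 CPM. The smooth muscle and pericyte list had a higher median (0.25, percentile 100) but went both ways, with 8 of 14 members above 0. The contractile genes Cnn1 (30.6, 25.1 and 73.7 CPM) and Actg2 (41.9, 51.3 and 146 CPM) were at least 2-fold higher, and the pericyte genes Kcnj8 (9.18, 26.5 and 19.9 CPM) and Notch3 were lower. Cell cycle genes did not stand apart (-0.03, percentile 21.3), nor did matrix genes (0.04) except with sums of transcripts (called higher, percentile 99.9), in which Thbs2 had 250.3, 177 and 425 CPM and Postn 842, 1297 and 617 CPM.

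**Figure D2:**
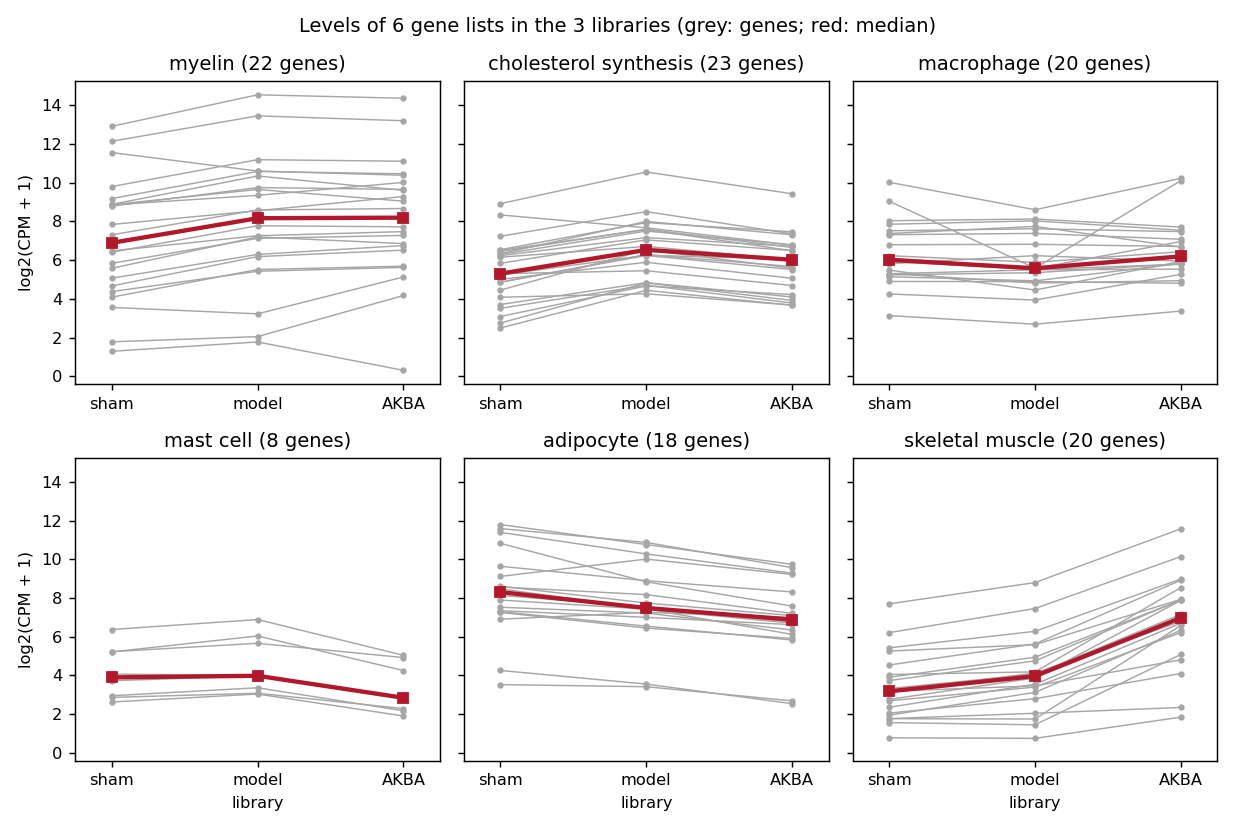
Levels of the members of 6 gene lists as log2(CPM + 1) in the sham, model and AKBA libraries (grey lines, 1 per gene) with their median (red squares), 1 library per group. Members of the mast cell list were lower in AKBA than in model in 8 of 8 cases and those of the skeletal muscle list higher in 20 of 20, whereas the macrophage lines cross, Gpnmb going from 527 to 47.0 and 1102 CPM.

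In all, 388 mRNA genes were at least 2-fold higher and 197 lower in AKBA than in model. The highest were the fast myosins Myh2 (log2 ratio 4.84) and Myh1 (4.35), Gpnmb (4.52), Lilrb4 (4.28), Rn45s (4.19) and the hair follicle gene Tchh (4.37; 4.22, 2.39 and 69.0 CPM). The macrophage elastase Mmp12 had 2.28, 0 and 63.1 CPM and the hair shaft gene Krtap7-1 0.0404, 0 and 18.2 CPM. Krt86, a hair keratin, had 5 counts in sham, 3 in model and 1532 in AKBA, with a counting interval of 7.44 to 11.3 for the log2 ratio of AKBA to model, and for Selenbp1 that interval was 8.12 to 15.9. The lowest were Fam111a (-3.52), Arhgef4 (-2.98), Col9a1 (-2.59), Grifin (-2.40; 88.1, 42.3 and 7.21 CPM), Faim2 (-2.23), the glutamate receptor gene Gria2 (-2.15; 21.4, 34.6 and 7.03 CPM), the mast cell protease gene Mcpt1l1 (-2.03; 186, 243 and 58.6 CPM), Hydin (-2.02), Grtp1 (-1.99) and Mpa2l (-1.97). Grtp1 changed sign with sums of transcripts (0.94).

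Of the 841 genes that differed at least 2-fold between model and sham, AKBA lay at least 2-fold back on the sham side of model in 126 (15.0%, exact 95% interval 12.6 to 17.6). That interval treats genes as independent, which they are not, and covers no spread between animals. Other settings gave shares from 12.2% (5 CPM filter) to 22.5% (sums of transcripts). Genes that moved back down were led by Fam111a, Arhgef4, Col9a1, Faim2 (4.91, 28.1 and 5.21 CPM) and Col9a2 (516, 3979 and 1085 counts). Genes that moved back up were led by Selenbp1, Rn45s (ribosomal RNA left after probe removal), Lilrb3, Lilrb4 and Gpnmb. Both comparisons use the same model library, which alone turns genes back. In simulated unchanged groups the share was 12.6% at a dispersion of 0.05 and 26.0% at 0.1. When the sham library took the place of the model library, 50.2% of the 841 genes had AKBA back on the model side, and of the 585 genes that differed between AKBA and model, sham lay back on the model side in 56.1%. Of the 652 genes higher in model, 342 were still at least 2-fold higher in AKBA than in sham (median log2 ratio 1.03), and of the 189 lower ones 80 were still lower (median -0.68). The overlap of higher in model with lower in AKBA was 50 genes, against 8.90 for independent lists, and that of the opposite directions 76 against 5.08. Part of either excess comes from the shared library. Over all 14427 genes, which are not independent replicates, the ratios of the 2 comparisons correlated at -0.25 with a covariance of -0.059, and simulated unchanged groups at a dispersion of 0.05 gave -0.49 and -0.089.

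AKBA against sham addressed how far the treated nerve stood from the uncrushed one. Myelin genes were higher, with 16 of 22 members at least 2-fold higher and a median of 1.13 above all genes (percentile 100). Cholesterol synthesis genes were at 0.33 (percentile 100), with 4 of 23 at least 2-fold higher. Adipocyte genes were lower, with 14 of 18 members at least 2-fold lower and a median of -1.54 (percentile 0), and muscle genes higher by a median of 3.70 (percentile 100). The mast cell list was lower (8 of 8 members below 0, percentile 0), as were the fatty acid synthesis (-1.40), fibroblast (-0.57), oxidative phosphorylation (-0.35) and NRF2 lists (-0.23, 10 of 20 members below 0). The keratinocyte (0.91), smooth muscle (0.85), immediate early (0.69), proliferation (0.60), endothelial (0.54), non-myelinating Schwann cell (0.53), ribosomal protein (0.19) and lymphocyte (0.55) lists were higher, the last at percentile 99.2, a call lost with sums of transcripts (97.3). In total 841 genes were at least 2-fold higher and 300 lower, or 579 and 435 with TMM scaling. The largest ratios were those of the muscle genes Mylpf (5.12), Myh2 (4.82), Myh1 (4.49), Myl1 (4.48) and Pvalb (4.39), and the lowest those of Scd (-4.79), Me1 (-4.19), Serpina12 (-3.76), the lipid gene Pnpla3 (-3.74; 399, 59.8 and 28.9 CPM) and Hydin (-3.47).

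Among lncRNA genes, a pair of rows, NONRATG020438.2 and NONRATG027982.1, held 29.8% of the counts in sham, 31.4% in model and 43.8% in AKBA, which lowers the CPM of all other lncRNA genes in the AKBA library. Of 1534 lncRNA rows with at least 1000 counts in every library, 2 repeated the exact counts of an mRNA row. NONRATG007649.2 had those of the ribosomal RNA row Rn18s (594246, 190854 and 464515 counts) and NONRATG025062.2 those of Cox14. Some lncRNA rows therefore need not stand for separate lncRNAs. In model 651 lncRNA genes were at least 2-fold higher and 286 lower than in sham, or 450 and 375 with TMM scaling and 365 and 443 with upper quartile scaling. In AKBA 188 were higher and 725 lower than in model, and with TMM scaling 360 were higher and 229 lower, so the direction of the balance depends on the scaling. Against sham, AKBA had 363 higher and 979 lower, or 612 and 579 with TMM scaling. NONRATG023252.2 (0, 111 and 77.9 CPM), NONRATG020804.2 (0, 59.4 and 68.5 CPM) and NONRATG020822.2 (0, 16.1 and 14.7 CPM) were at 0 in sham only. NONRATG000285.2 (log2 ratio -4.11; 61.1, 2.58 and 30.2 CPM), NONRATG027481.2 (15.6, 0 and 8.31 CPM) and NONRATG002904.2 (212, 2 and 342 counts, counting interval of the log2 ratio of model to sham -10.03 to -5.10) were lowest in model. For AKBA against model the highest were NONRATG018241.2 (0, 0 and 443 CPM), NONRATG004818.2 (0, 0 and 21.1 CPM) and NONRATG003531.2 (4.17; 0.364, 1.53 and 44.5 CPM). The lowest were NONRATG023164.2 (57.8, 92.3 and 0 CPM), NONRATG017701.2 (7.53, 7.31 and 0 CPM) and NONRATG005933.2 (-3.02; 0.208, 9.37 and 0.276 CPM). For AKBA against sham, NONRATG003087.2 (-5.65; 14179, 1689 and 282 CPM) and NONRATG018055.2 (-4.13; 118, 18.2 and 5.80 CPM) were also among the lowest.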

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

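Each value below comes from 1 library per group, so no replicate could be left out. No paired analysis was possible because each group has a single library and no pair of groups shares 2 replicate numbers. The lncRNA sums of transcripts were not run, since the sources used here do not map the lncRNA transcripts to genes. Leaving out ribosomal RNA, genes at 0 or the longer muscle list, and adding the totals, were chosen after seeing the data. Of the values that answer a comparison, 680 stayed within their interval or within 1.5 times the count, and 73 moved. The interval was the counting interval for ratios and the exact binomial interval over genes for shares. The latter is wide for short lists, such as 23.1 to 68.5% for macrophage genes in model against sham. For the other values 773 stayed, 9 moved and 1, Grtp1 in AKBA against model, changed sign with sums of transcripts (0.94). Where a value moved, the cause was not tested unless the setting itself changes which genes pass.

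With a pseudocount of 0.1, which lets low genes through, 295 mRNA genes were lower in model than in sham and 311 lower in AKBA than in model, lncRNA genes numbered 1355 higher and 817 lower, 454 and 1799, and 786 and 2023 in the 3 comparisons, and 18.0% of genes moved back. At a mean of at least 5 CPM, which leaves fewer genes, 206 mRNA genes were higher in AKBA than in model, lncRNA genes numbered 335 and 79, 67 and 363, and 179 and 506, and 12.2% moved back. The share of members above 0 was 100% for immediate early genes in model against sham and 0% for leukotriene and red cell genes in AKBA against model.

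With TMM scaling, model against sham gave 376 higher and 293 lower mRNA genes, the lncRNA counts were 360 and 229 for AKBA against model and 612 and 579 for AKBA against sham, and 19.6% of genes moved back. The share of members above 0 in model against sham was 10% for macrophage, 50.0% for MHC class II, 20.0% for complement, 23.1% for matrix, 10.5% for oxidative phosphorylation and 45.8% for ribosomal protein genes, and 91.7% for the last in AKBA against model. Upper quartile scaling gave 395 higher mRNA genes in model against sham, 365 and 443 lncRNA genes in that comparison and 350 and 228 in AKBA against model, 19.5% moved back, and shares of 15.0%, 50.0%, 20.0%, 23.1%, 10.5% and 54.2% for the same lists in the same order, with 91.7% again for ribosomal proteins in AKBA against model. Sums of transcripts gave 298 lower in model than in sham, 330 lower in AKBA than in model, 22.5% moved back and 0% of leukotriene genes above 0 in AKBA against model.

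At 1.5-fold the mRNA counts were 2162 higher and 552 lower, 806 and 776, and 2544 and 841, and at 4-fold 41 and 25, 140 and 22, and 133 and 45. Without ribosomal RNA rows 17.8% moved back, and the shares were 10.5% for oxidative phosphorylation and 70.8% for ribosomal protein genes in model against sham and 91.7% for the latter in AKBA against model. That setting also split model against sham 502 to 244. With the mRNA and lncRNA totals added, lncRNA counts were 164 and 47, 96 and 66, and 198 and 126. List calls changed most with sums of transcripts, 12 of 93, and least without the longer muscle list, 0 of 93. Among these, sums of transcripts ended the calls of the non-myelinating (percentile 94.6), axon (97.3), neutrophil (5.82) and fibroblast (5.69) lists in model against sham and of the lymphocyte list in AKBA against sham (97.3). Only 31063 of 55767 transcripts were placed in genes, so changes with sums of transcripts can come from the transcripts left out. Depth limits genes near the 1 CPM filter most.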

Other observations

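Some groups have not been described so far. In model against sham, the Schwann cell injury list (median -0.07 relative to all genes, percentile 25.7), mast cell (0.23, percentile 93.6), lymphocyte (0.14, percentile 86.1), MHC class II (0.01, percentile 54.5), inflammatory (0.05, percentile 69.5), interferon (0.09, percentile 81.7), ERK feedback (0.06, percentile 73.6), YAP target (0.13, percentile 92.4), ribosomal protein (0.03, percentile 77.3) and keratinocyte lists (0.22, percentile 84.6) had no call with the settings used in the report. Some of them had one under other settings. The Schwann cell injury list was called lower with no level filter (percentile 0.59) and without ribosomal RNA rows (percentile 0.83) but higher at the 5 CPM filter (percentile 98.5), so no direction is given for it. The inflammatory list was called lower with no level filter (percentile 1.10) and with sums of transcripts (percentile 0.18), the lymphocyte list higher with no level filter (percentile 98.3) and the YAP target list higher with sums of transcripts (percentile 99.1). Single members past 2-fold included Shh, the endothelial adhesion gene Sele at 4.48, 20.1 and 15.6 CPM in sham, model and AKBA, and Ajuba at 18.8, 46.0 and 42.2 CPM. In AKBA against model, lymphocyte (0.35, percentile 96.2), MHC class II (-0.03, percentile 36.7), complement (0.01, percentile 81.6), ERK feedback (-0.02, percentile 34.0), YAP target (-0.08, percentile 23.3), NRF2 (-0.11, percentile 4.24), neurotrophic (-0.07, percentile 17.3) and oxidative phosphorylation lists (-0.03, percentile 52.6) did not stand apart either. In AKBA against sham the Schwann cell injury list (0.06, percentile 64.4) was called higher with no level filter (percentile 99.3), at the 5 CPM filter (100) and with sums of transcripts (98.8), the interferon list (0.20, percentile 95.4) higher with sums of transcripts (97.7) and the complement list (-0.24, percentile 3.13) lower with no level filter (2.20). In AKBA against model, ribosomal protein genes (0.19, percentile 100) and keratinocyte genes (0.54) were called higher, the latter without its call at a pseudocount of 0.1 (percentile 97.3), without the muscle, fat and blood lists (97.3) and without ribosomal RNA rows (97.4). Cd8a stood at 2.24, 1.85 and 8.23 CPM, complement C3 at 16.0, 13.8 and 49.6 CPM, the cystine transporter gene Slc7a11 at 11.3, 9.76 and 33.8 CPM, and Ankrd1 at 0.634, 1.32 and 13.1 CPM.

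LOC108351097, singled out after its values were seen, had 0, 0 and 81422 counts. The RefSeq table names it Rn45sl1, after the ribosomal RNA precursor. Apoe, also singled out afterwards, was at 3039, 1379 and 5766 CPM.

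The tests in the next 3 paragraphs were chosen after the result was seen, except those of further hair shaft genes and of further lipid-laden macrophage genes, whose bounds were set before those genes were looked at. With 1 library per group, an effect of AKBA or of the crush stays open in each, untested.

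Skeletal muscle transcripts in the AKBA library may come from muscle carried over with the nerve, but of 80 further muscle genes outside the fixed list, 54 (67.5%) were at least 2-fold higher in AKBA than in model, short of the 75% set for that reading. Several of the rest, such as Tpm3 and Slc25a4, were abundant in model already (149 and 224 CPM), so carried-over muscle and a change within the nerve cannot be told apart. Over 8 genes of regenerating muscle, 5 of them below the level filter, the median log2 ratio was 1.06 against model and 0.56 against sham, so regenerating fibres beside mature ones stay open. Myog (0, 0 and 141 counts), Myod1 (0, 0 and 63), Chrng (0, 0 and 25) and Tmem8c (0, 0 and 23) were counted in AKBA alone and Myh3 (4, 41 and 1202) and Myh8 (0, 25 and 923) mostly there, while Myf5 (0, 7 and 11) and Myl4 (280, 74 and 339) were not. Of 25 further hair shaft genes, 14 had at least 100 counts in AKBA against 2 in model and 2 in sham, Krt31 with 0, 0 and 892 counts, so hair or skin in that sample is a candidate source of these hair transcripts.

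Gpnmb, Lyz2 and Cd68 were high in sham and AKBA and low in model. More macrophages in AKBA than in model cannot be told apart from a change within them. The fixed list holds Gpnmb, Lyz2 and Cd68 themselves. Its 20 genes went both ways, with a median log2 ratio of 0.20 and a range from 4.52 (Gpnmb) to -1.06 (Cd163). Among broad macrophage genes, Csf1r (-0.42), Mrc1 (-0.49) and Adgre1 (-0.28) were lower in AKBA than in model. Itgam (0.45), Cx3cr1 (0.68) and Msr1 (0.27) were higher. A wider lipid-laden programme was tested on 28 further lysosomal and lipid-handling genes, whose median in AKBA against model lay 0.39 above all genes (percentile 100; 25 of 28 above 0), with Lipa at 38.2, 22.5 and 88.3 CPM, Abca1 at 283, 179.7 and 579 CPM and Itgax at 6.63, 4.39 and 20.8 CPM. That is short of the 0.5 set in advance, and Cd36 (491, 441 and 285 CPM) was lower in AKBA than in model. In model against sham the 28 had a median log2 ratio of 0.00 (-0.18 relative to all genes, percentile 1.29), far less than the fall of Gpnmb, with Spp1 (504, 925 and 624 CPM), Cd9 (407, 651 and 808 CPM) and Syngr1 (7.01, 14.6 and 19.2 CPM) higher there, so a shared programme remains a hypothesis for part of the genes.

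Myelin and Schwann cell genes were higher in model than in sham. Fat in the sham library diluting every other cell type alike would shift all of them equally, but the myelin and fibroblast medians lay 1.41 apart on the log2 scale, and the lower quartile of the first (0.73) was above the upper quartile of the second (0.27). Ribosomal RNA left over in sham is too little to account for it, since leaving those rows out of the totals moved the myelin median, taken without reference to all genes, from 1.26 to 1.14. More outer sheath and fat in the sham piece, with less of the inner nerve, may be part of it. The endothelial and perineurial medians, 2 of the 3 tested, lay within the quartiles of the myelin list, and the non-myelinating one lay below them, so sampling of the nerve and the crush itself cannot be told apart. A mislabelled library was not tested.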
